A study of Mus musculus with 18 samples.

How the data were processed

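The series held 18 mouse RNA-seq samples in 9 groups of 2, made from polyadenylated RNA and sequenced on an Illumina HiSeq, per the labels' protocols. Bone marrow derived macrophages treated with 100 ng/ml lipopolysaccharide for 3 hours were among them and were not analysed here. The other 7 groups entered 5 comparisons, each in 1 table deposited by the authors. Tools named in the submitters' processing notes were CASAVA 1.8 and DESeq, without a version, and the genome build named there was GRCm38 (mm10). The aligner, the read counter, its strand setting and the annotation release were not given in the sources used here.

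Each table held the signal of each gene as 1 normalised read count per group, which the authors made as a mean over the 2 libraries of the group, so no SD or n is attached to it. The log2 fold change was deposited by the authors as the first-named group over the second, and was recomputed here from the deposited means. It differed from the deposited value by rounding alone, and was taken from the means where 25 cells of the B cell table and 12 of the T cell table held a spreadsheet error in place of a value. The p-value and the adjusted p-value were those the authors deposited, from DESeq per the submitters' processing notes. The tables listed called genes only: the largest adjusted p in each table was under 0.05. The number of genes tested was recovered from the relation of p, its rank and the adjusted p under Benjamini-Hochberg adjustment. The B cell table ended with 31 names without values, all of them listed above with values, which were left out. No table had a column of values of a single sample.

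The design fixed before the data were examined allowed for counts per library, tested with edgeR, and for tables of the authors' own comparisons, and the second case applied. Genes were counted as called at the authors' adjusted p under 0.05, with no test added. A count model on the called genes alone would rest on genes selected for their difference, and was not run. Of 49 gene lists fixed before the data were examined, those with at least 3 called members in a comparison were tested for direction, higher against lower among members and among the other called genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 102 tests. A value adjusted over the list alone could not be given, because the tables list only called genes. Tested on simulated data, with random directions for lists of 10 genes, the unadjusted test fell under 0.05 in 1.75% of draws in B cells, 4.1% in T cells, 4.15% in lymph node, 1.35% in tumour against knockout lymph node and 4.15% in tumour against wild-type lymph node. Overlaps of called genes were set beside the product of the list sizes over the genes tested, by direction. Positions came from GENCODE release M21 on GRCm38, in which 294, 582, 105, 416 and 1623 of the called genes of the B cell, T cell, lymph node and both tumour tables were found. The position of Becn2 came from a RefSeq gene table of the same build.

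Means over 2 libraries printed with 10 or 15 significant digits still hold the whole reads of each library. For each group the pair of step sizes was searched that writes each mean as whole, non-negative reads of both libraries. A first rule for choosing among such pairs recovered few of the simulated reads and gave reads that did not match between tables, and it was replaced, after that was seen, by the pair with size factors nearest 1. With it all solved reads were right in each of the 10 simulated groups, and 430 of 430 genes listed in 2 tables had the same reads for the shared group in both. Reads were solved for both groups in 288 of 298 genes in B cells and 510 of 587 in T cells, and for every gene in the other tables. The remaining genes fitted more than 1 pair of reads and have no reads per library. Recovered libraries carry no replicate number and entered no test between groups. They gave the spread behind a mean, folds with 1 library left out, and the division of salivary gland reads between libraries in the closing part. A fold against a group at 0 reads was given as a lower bound from 3 reads over the group, and with 1 to 3 reads as a ratio with an exact 95% interval.

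Named genes followed a rule fixed before the data were examined. It took Becn2 and Becn1, then per comparison the 10 largest rises and falls with a finite fold change and a mean of at least 50 in the higher group, leaving out receptor segments, predicted genes and unnamed genes, the 3 genes of smallest adjusted p per direction, and the 4 members of smallest adjusted p of each list with at least 3 called members. Genes shared by 2 comparisons were named in full up to 10, otherwise the 5 with the largest smaller fold. A gene that this rule gives is not reported here. Igkv1-135 was named beyond it, after its values were seen. Which of the genes this rule gives were printed, and which were set side by side in the closing part, was decided after their values were seen. Alternatives were an adjusted p under 0.01, a fold of at least 2, a mean of at least 50, named genes only, a pseudocount of 1, matching by symbol, and windows of 5 and 20 Mb. Leaving out each library in turn, on recovered reads and for folds alone, was added after the data were seen, and is given beside named genes whose fold moved by over 1.5 times. So was leaving genes called in all 3 tissues out of the natural killer list in T cells. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.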

Results

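Messenger RNA was sequenced from mice lacking Beclin 2, a relative of the autophagy protein Beclin 1, and from wild-type mice, in 18 samples that formed 9 groups of 2. The comparisons covered splenic B cells and splenic T cells from mice aged 8 weeks, lymph nodes of both genotypes, and lymphoma tissue from knockout mice. No age was given for the mice of the lymph nodes and tumours, so a difference in age between these groups cannot be excluded. The labels gave the strain of every sample as C57BL/6 and did not say that the 2 samples of a group came from separate animals, so p-values measured only the spread between these samples, which may be technical. The authors' deposited tables, 5 in number, listed for each comparison the genes called at an adjusted p under 0.05, with 1 mean normalised read count per group. Total reads per library could not be read from tables of called genes alone, and the depth was known only as size factors recovered from the means, which ran from 0.842 to 1.19. Precision at low counts was therefore described by the reads recovered per library, and intervals and floors given for these reads cover counting error only.

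The targeted gene came first. Neither Becn2 nor Becn1 was listed in any of the authors' deposited tables, so the tables gave no level of the targeted transcript in any sample and did not check the genotype labels. No gene of the autophagy list was called by the authors' DESeq test in B cells, T cells, lymph node or tumour against knockout lymph node, and the number at an unadjusted p under 0.05 could not be given because only called genes were listed. In tumour against wild-type lymph node, Atg14 (log2 fold change 0.69) and Calcoco1 (0.51) were higher and Gabarap (-0.50) was lower in the authors' deposited table. No transcript of the sex-linked list was called by that test in any comparison, again with no unadjusted count to be had.

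**Figure D1:**
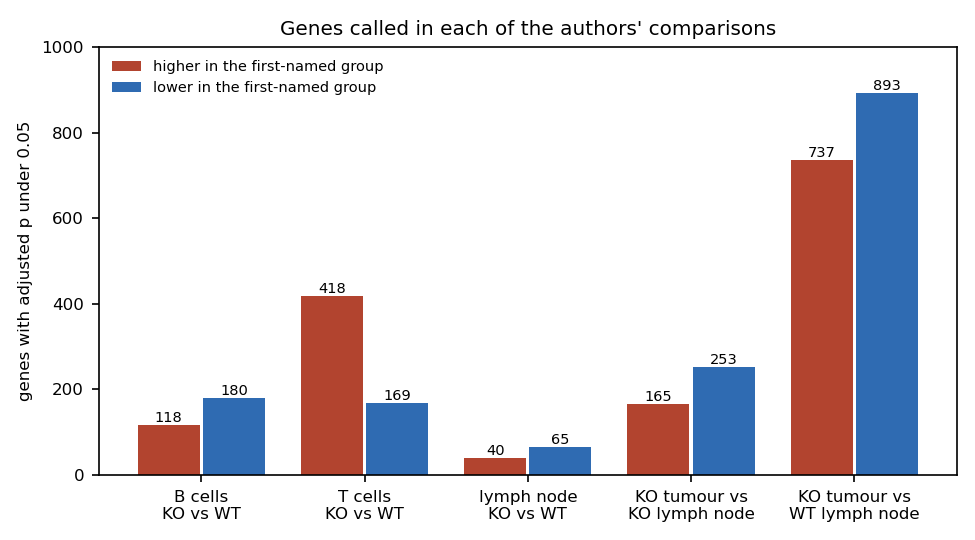
Number of genes (vertical axis) with an adjusted p under 0.05 in each of the authors' 5 comparisons (horizontal axis). Red bars count genes higher and blue bars genes lower in the first-named group, from 40 higher in knockout lymph node to 893 lower in tumour against wild-type lymph node.

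Which transcripts differ in B cells without Beclin 2 was the first comparison. Knockout B cell preparations held less mRNA of called natural killer cell genes than wild-type B cell preparations. They held more of the called members of the germinal centre and interferon-stimulated lists. The purity of the preparations was not known, so the natural killer transcripts cannot be assigned to B cells or to other cells among them. All 19 called natural killer genes were lower in the authors' deposited table, including the granule protease Gzma (log2 fold change -1.96) and the receptors Klra8 (-2.27), Klra4 (-2.34) and Klrc2 (-2.14). Klra8 and Klra4 are also on the list of transcripts known to vary between mouse substrains. All 7 called germinal centre genes were higher in the authors' deposited table, with Gcsam at 2.82, Nuggc at 1.95 and Basp1 at 1.64. All 7 called interferon-stimulated genes were higher too, and the authors' deposited table gave Ifi44 at 3.19 and the oligoadenylate synthetases Oas1a, Oas2 and Oas3 at 1.70, 1.40 and 1.19. The 7 also held Oas1g and Oasl1, of the same family. Interferon-inducible genes of a cluster on chromosome 1, not on that list, went both ways in that table. Pydc4 (-4.75), Pydc3 (-1.46) and Pyhin1 (-0.95) were lower, and Ifi204 (2.45) and Mnda (1.66) were higher.

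Immunoglobulin segments moved in both directions in B cells, 18 higher and 34 lower. In the authors' deposited table all 15 called kappa variable segments were higher, such as Igkv13-84 (3.66) and Igkv3-5 (4.92), while 33 of 34 called heavy chain variable segments were lower. Ighv1-80 had 0 reads in both knockout libraries against a mean of 639.9 normalised reads in wild type, at least 390.2-fold lower when 3 reads over the group are taken as the floor. The constant regions Ighg3 (6.08) and Ighe (5.34), used by switched antibodies, were the largest rises by the rule for named genes in the authors' deposited table. Outside these families the largest falls by the rule for named genes, which leaves out predicted genes, were Lyz2 (-6.55), the lysozyme of myeloid cells, Pydc4 (-4.75), BC147527 (-4.42), Hcrtr2 (-3.53) and Serinc3 (-2.98), and the rises included Chst1 (4.29), Xkr6 (4.18), Lyz1 (3.93), the second lysozyme gene, and Gnaz (3.37), all from the authors' deposited table. With 1 recovered library left out at a time, the log2 fold change ran from 4.63 to 6.83 for Ighe, from 3.49 to 4.55 for Lyz1, from -8.95 to -5.69 for Lyz2, from -5.30 to -3.88 for BC147527 and from -4.12 to -3.11 for Hcrtr2. Each of these moved most without the library that held more reads in the lower group. The reads then left there were 2 for Ighe, 3 for Lyz2 and 3 for BC147527, with 95% exact counting intervals from 4.97 to 9.89, from -11.23 to -7.41 and from -7.59 to -3.74.

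In total 298 of about 23957 genes tested were called in B cells, 118 higher and 180 lower. Two-sided Fisher's exact tests of list members against the other called genes, with Benjamini-Hochberg adjustment over 102 tests, gave adjusted p = 0.000658 for natural killer genes and 0.0088 for both germinal centre and interferon-stimulated genes. Lists that did not pass were immediate-early genes (0 higher, 8 lower, adjusted p = 0.0871), ERK targets (0 and 6, 0.210), effector and memory T cell genes (1 and 8, 0.210), inflammatory cytokines (0 and 3, 0.453), NF-kB targets (0 and 3, 0.453) and immunoglobulin segments (0.660). In all 288 genes with reads recovered for both groups, the knockout and wild-type libraries did not overlap. Random orders of 2 and 2 libraries part in 33.3% of genes, and calling selects such genes, so this is not independent evidence. Without receptor segments and predicted genes 114 of the 180 lower genes were left. These list tests treat genes as independent, which they are not. Reads of the Klra, Ighv, Igkv and Pydc families, and of the pair Lyz1 and Lyz2, can be divided among near-identical copies.

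For T cells the same question gave a coordinated fall of ribosomal protein genes. All 32 called cytosolic ribosomal protein genes were lower in knockout T cells in the authors' deposited table, with Rpl3 at -1.26, Rps15a at -0.75, Rps29 at -0.70 and Rpl26 at -0.65. T cell receptor segments were lower in 9 of 10 called cases, including Trav7-3 (-3.98) and Trav14d-1 (-2.09) in the authors' deposited table, the second of them from -3.02 to -1.53 with 1 recovered library left out, and lowest without the knockout library with more reads. Natural killer genes were lower in 4 of 4, with Klra7 (-1.97), Xcl1 (-1.20) and Klra1 (-1.74), the last also lower in B cells and lymph node, and the immediate-early genes Ppp1r15a (-0.97), Junb (-0.81), Klf6 (-0.74) and Ier2 (-0.58) were lower in the authors' deposited table. Immunoglobulin segments, transcripts of B lineage cells, were higher in 80 of 95 called cases, with all 46 kappa variable segments higher and the 38 heavy chain variable segments divided into 23 higher and 15 lower. The authors' deposited table put Igkc, the kappa constant region, at a mean of 167672 normalised reads in knockout and 25120.5 in wild type.

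Transcripts of other cell types were also called in the T cell preparations. Plasma cell genes were higher in 11 of 11, with Derl3 at 2.64, Sdc1 at 1.93 and Xbp1 at 1.57 in the authors' deposited table. Monocyte and macrophage genes were higher in 15 of 16, including Fcgr4 (2.25) and Cd5l (1.67), and the exception was Lyz2 (-5.61) in the authors' deposited table. Lyz1 was higher there (2.89), and reads can be divided between this pair of copies. With 1 recovered library left out, Derl3 ran from 2.20 to 3.27, Sdc1 from 1.52 to 2.52, Cd5l from 1.16 to 2.46 and Lyz2 from -6.26 to -5.17, each moving most without the library with more reads in the lower group. Granulocyte transcripts Elane (3.17), Mpo (2.69) and Prss34 (4.29), the latter a basophil protease, were higher in the authors' deposited table. Checkpoint and follicular helper genes were called higher, among them Lag3 (1.84), Tigit (1.44), Pdcd1 (1.15) and Il21 (2.32), and the naive T cell genes Sox4 (-0.85), Tdrp (-0.73) and Dapl1 (-0.71) were lower in the authors' deposited table. Ifi202b, an interferon-inducible gene of chromosome 1, had 136 and 137 reads in the knockout libraries against 0 and 1 in wild type, a ratio of 221 with a 95% exact counting interval from 39.3 to 8748 and a log2 fold change of 6.37 with 1 added to both means in place of 7.79.

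In T cells 587 of about 25015 genes tested were called, 418 higher and 169 lower. Fisher's exact tests gave adjusted p = 5.2e-17 for ribosomal proteins, 0.000891 for receptor segments, 0.0113 for immunoglobulin segments and 0.0347 for natural killer and for immediate-early genes. Plasma cell (0.133), monocyte (0.157), neutrophil (0.194), interferon-stimulated (8 higher, 0 lower, 0.240), lysosome (8 and 0, 0.240), follicular helper (6 and 0, 0.351), checkpoint (5 and 0, 0.515) and naive T cell lists (0 and 3, 0.0871) did not pass as lists. With most called genes higher in T cells, 10 members all higher give an unadjusted Fisher's exact p of 0.0702. Lists of up to 10 called genes, all higher, therefore could not pass, and their failure carries no information. The immunoglobulin call was lost among genes with an adjusted p under 0.01 (adjusted p = 0.0701) and among genes at least 2-fold apart (0.390). The immediate-early call was lost under the first of these (0.0766) and could not be tested under the second, because all 4 called members were less than 2-fold apart. These settings left 105 and 85 of the 169 lower genes. The natural killer call, on 4 genes, was lost without Klra1, which was called in all 3 tissues (adjusted p = 0.0871 for the 3 left). In all 510 genes with reads recovered for both groups the libraries of the 2 genotypes did not overlap, against the 33.3% of random orders.

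**Figure D2:**
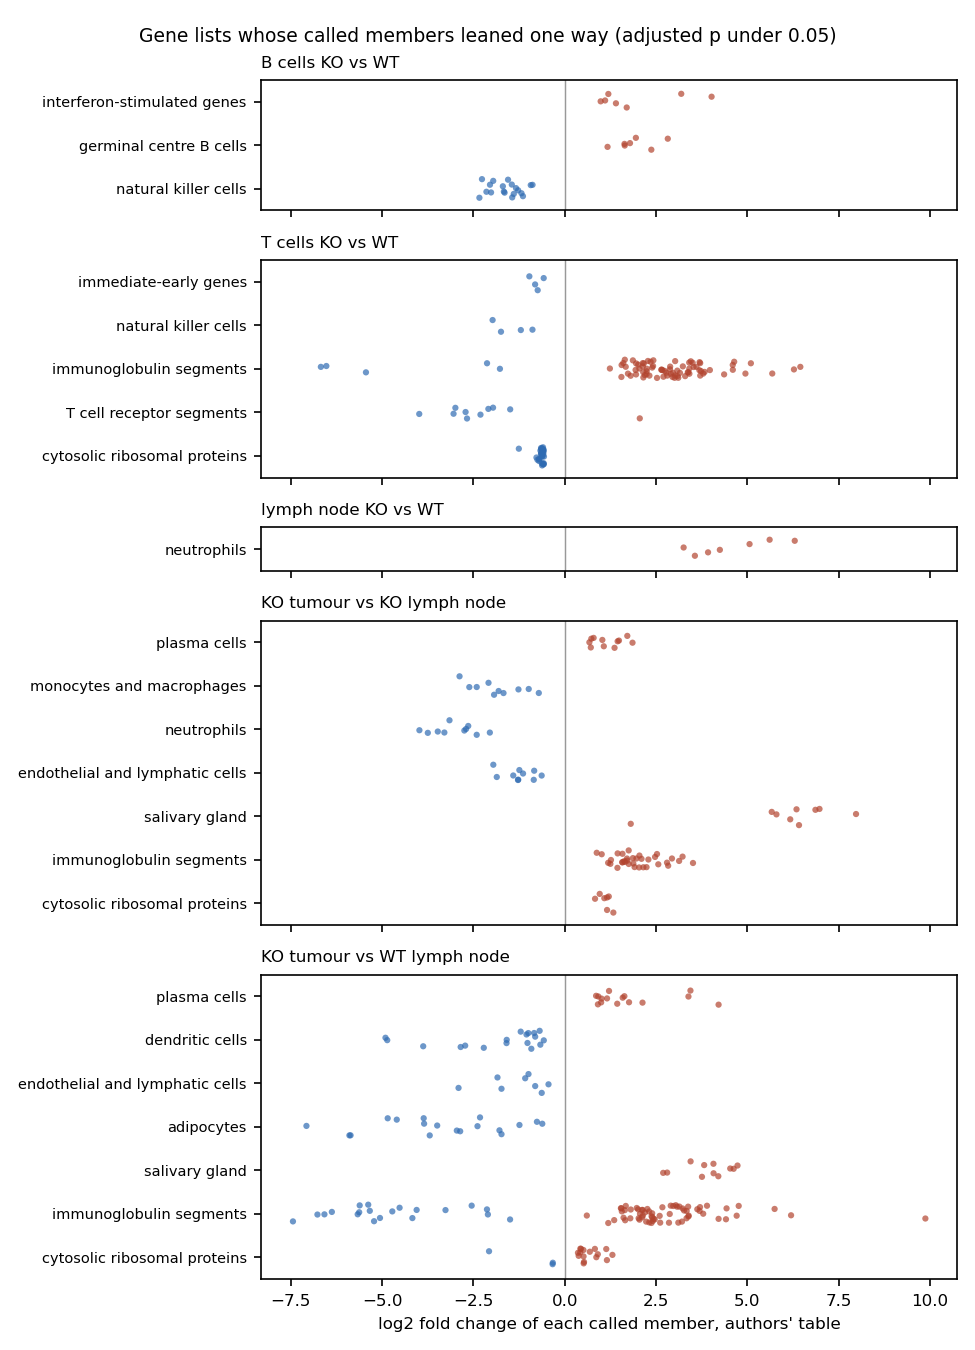
Log2 fold change in the authors' deposited tables (horizontal axis) of each called member of the 23 list and comparison pairs with an adjusted p under 0.05 (vertical axis), red for higher and blue for lower in the first-named group, with vertical scatter added for legibility. Members with a group mean of 0 have no finite fold change and are not drawn, and all 32 ribosomal protein genes of T cells lie below 0.

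Knockout lymph nodes were compared with wild-type lymph nodes for the same effect in whole tissue. Neutrophil genes were higher in 8 of 8 called cases, and the authors' deposited table gave the calprotectin subunits S100a8 and S100a9 at 5.06 and 3.92, and the granule proteins Ltf at 6.30, Ngp at 5.61 and Lcn2 at 4.25. Reads of Ltf and Ngp in wild type came from 1 library, with 0 and 5 reads of Ltf against 332 and 120 in knockout, and 0 and 9 of Ngp against 306 and 184. Without that library wild type was at 0, and without the other the log2 fold change was 5.30 for Ltf and 4.61 for Ngp. Retnlg, another neutrophil transcript, had 114 and 93 reads in the knockout libraries and 0 in both wild-type libraries, at least 64.8-fold higher. Of the lysozyme transcripts, Lyz2 fell from a mean of 30386 normalised reads in wild type to 299.7 and Lyz1 rose from 4113 to 18818 in the authors' deposited table. Reads can be divided between these neighbouring copies on chromosome 10, so the level of either is uncertain. The 121 and 451 reads of Lyz2 in the knockout libraries gave a log2 fold change from -8.21 to -5.93 with 1 library left out, lowest without the knockout library with more. Adipose transcripts Cfd (-4.27), Pck1 (-3.00), Car3 (-1.86) and Cidec (-1.62) were lower, as were the class II presentation genes H2-DMb2 (-0.71), Cd74 (-0.56) and H2-Ab1 (-0.55) in the authors' deposited table. Pck1 ran from -3.83, without the knockout library with more reads, to -2.47 with 1 library left out. B cell genes Fcer2a (-0.88), Pax5 (-0.75) and Cd79a (-0.59) were lower while Ighg2b (1.69) and Igkc (1.20) were higher in the authors' deposited table.

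Of about 22105 genes tested in lymph node, 105 were called, 40 higher and 65 lower. The neutrophil list passed Fisher's exact test (adjusted p = 0.00234). The lists of monocytes and macrophages (4 higher, 1 lower, adjusted p = 0.194), class II presentation (0 and 3, 0.455), adipocytes (1 and 4, 0.805), B cell identity (1 and 3, 1) and immunoglobulin segments (13 and 20, 1) did not. Receptor segments and predicted genes made up a large part of this list, and 65 genes, 25 higher and 40 lower, were left without them. All 105 genes had libraries of the 2 genotypes that did not overlap, against 33.3% of random orders.

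Lymphoma tissue from knockout mice was then set against knockout lymph node, which asks what differs in the tumour at the same genotype. All 35 called immunoglobulin segments were higher in the authors' deposited table, among them Igkv5-43 (2.15), Igkv1-110 (2.04), Igkv6-15 (1.87) and Ighg2b (1.71). Plasma cell genes were higher in 11 of 11, with Derl3 at 1.48 and Mzb1 at 1.03, and 7 of 7 ribosomal protein genes were higher, with Rps28 and Rpl37 both at 1.16 in the authors' deposited table. Salivary gland transcripts were higher in 10 of 10, and the authors' deposited table placed the proline-rich protein Prb1 at 7.98 (7.34 with 1 added to both means), Dcpp1 at 6.86, Lpo at 6.41 and the carbonic anhydrase Car6 at 6.35. Bpifa2, of the same list, reached 159028 and 433638 normalised reads in the tumour libraries. Whether the source of the salivary reads also added to the plasma cell genes, here or against wild-type lymph node, was not tested. The sizes for Dcpp1 and Car6 rested on 1 knockout node library, which had 149 reads of Dcpp1 and 315 of Car6 against 1 and 13 in the other. Without it the log2 fold change was 12.71 for Dcpp1, with a 95% exact counting interval from 10.23 to 18.01, and 9.64 for Car6, and the lowest values without 1 library were 5.88 and 5.42. Prb1 had 4 and 0 reads in the node libraries and was at 6.98 without the library at 0, with no finite value without the other, and Lpo ran from 5.73, without the tumour library with more reads, to 6.87. Gzmk, a granzyme of T cells, was also higher at 2.80 in the authors' deposited table, and from 2.31 to 3.55 with 1 library left out, highest without the node library with more reads.

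Myeloid and endothelial transcripts were lower in the tumours than in knockout lymph node. Neutrophil genes fell in 10 of 10 called cases, with Mmp9 at -3.75, Lcn2 at -3.30 and S100a9 at -3.15 in the authors' deposited table. The tumour libraries were unequal in these genes, with 131 and 7 reads of S100a9, 27 and 10 of Lcn2 and 39 and 17 of Mmp9. Without the library with more reads the log2 fold changes were -6.41, -4.14 and -4.43, and the smallest falls with 1 library left out were -2.23, -2.76 and -3.29. The knockout node itself was high in these genes, with S100a9 at a mean of 555 normalised reads against 36.6 in wild-type node in the authors' deposited table, and 3 neutrophil genes were called lower in tumour against wild-type lymph node, S100a9 not among them. Macrophage genes fell in 10 of 10, including the scavenger receptors Marco (-2.88) and Msr1 (-2.61) and the sinus macrophage lectin Siglec1 (-1.81), and endothelial genes fell in 10 of 10, including Cldn5 (-1.96), Prox1 (-1.41) and Kdr (-1.28) in the authors' deposited table. Single stromal, dendritic and mast cell genes were lower as well, namely Cxcl13 (-2.43), Enpp2 (-1.51), Ccl22 (-4.27), Fscn1 (-1.93), Cma1 (-3.59) and Tpsb2 (-3.22) in the authors' deposited table. The largest falls by the rule for named genes were Bpifb3 (-6.10), Bpifb2 (-5.61) and Cd209e (-5.27), and Col6a5 (-3.33) had the smallest adjusted p in the authors' deposited table. Tpsb2 had 60 and 2 reads in the tumour libraries and ran from -7.13 (95% exact counting interval from -10.18 to -5.27) to -2.27 with 1 library left out, and Cma1 had 41 and 0, with -2.59 without the library at 0 and no finite value without the other. Siglec1 ran from -2.71 to -1.26, Ccl22 from -5.00 to -3.75, Bpifb2 from -6.79 to -4.97 and Cd209e from -6.81 to -4.54, each lowest without the tumour library with more reads. The lowest values rested on 3 reads for Bpifb2 and 1 for Cd209e, with 95% exact counting intervals from -9.08 to -5.24 and from -12.12 to -4.31. Bpifb3 ran from -6.60 to -5.34, the latter without the node library with more reads.

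The authors called 418 of about 23565 genes tested, 165 higher and 253 lower. Fisher's exact tests gave adjusted p = 3.4e-14 for immunoglobulin segments, 0.000455 for plasma cell, 0.000879 for salivary gland and 0.0088 for ribosomal protein genes, and 0.0347 each for neutrophil, macrophage and endothelial genes. Dendritic cell (0 higher, 7 lower, adjusted p = 0.15), interferon-stimulated (4 and 0, 0.0871), lymph node stroma (0 and 6, 0.210), mast cell (0 and 5, 0.317) and adipocyte lists (0 and 5, 0.317) did not pass. The calls of macrophage and endothelial genes were lost among genes with an adjusted p under 0.01 (0.145 for each) and among genes at least 2-fold apart (0.103 and 0.163), where the neutrophil call was lost too (0.0587), and 273 genes, 159 of them lower, had an adjusted p under 0.01. All 418 genes had libraries of the 2 groups that did not overlap, against 33.3% of random orders.

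**Figure D3:**
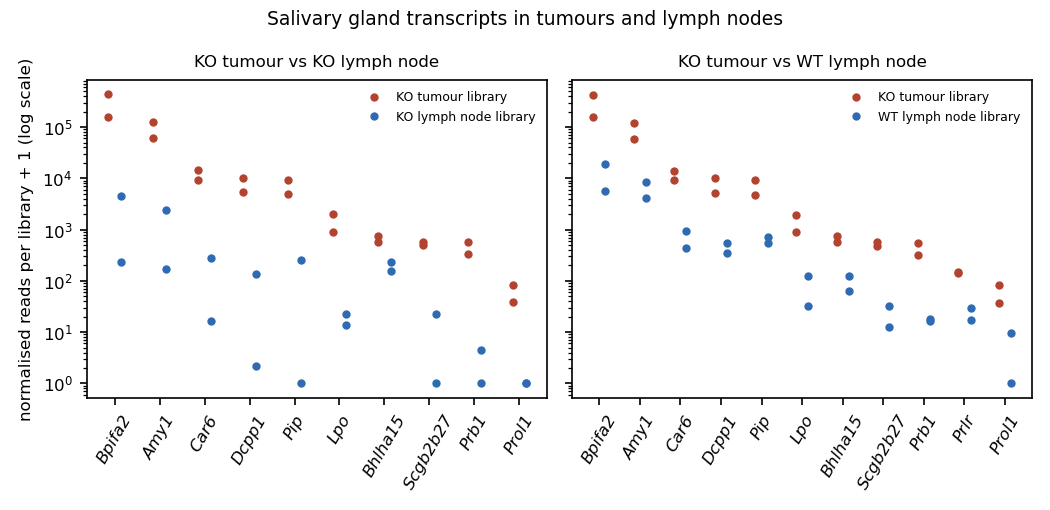
Normalised reads per library plus 1 (vertical axis, log scale), recovered from the authors' group means, for each called salivary gland gene (horizontal axis). Red points are the 2 tumour libraries and blue points the 2 lymph node libraries of the comparison, with 10 genes against knockout node and 11 against wild-type node, and the tumour libraries lie above the node libraries for every gene drawn.

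Against wild-type lymph node the tumours differed in genotype as well as tissue, and this comparison held the most called genes. Immunoglobulin segments were higher in 67 of 89 called cases, with the smallest adjusted p for Igkv3-4 (3.39), Igkv16-104 (3.04) and Igkv3-12 (3.08), and plasma cell genes were higher in 15 of 15, including Ighg3 (4.21) and Mzb1 (1.76) in the authors' deposited table. Salivary gland genes were higher in 11 of 11, with Scgb2b27 at 4.62, Car6 at 4.07 and Bhlha15 at 2.80, and ribosomal protein genes in 16 of 19, with Rpl38 at 1.31 and Rpl37 at 1.14 in the authors' deposited table. Adipocyte genes were lower in 18 of 18, and the authors' deposited table gave the adipokine Cfd at -7.07, Pck1 at -5.89, Car3 at -4.60 and Cidec at -3.70. Dendritic cell genes were lower in 18 of 18, with Cd209a at -4.91, Ccl22 at -4.86, Siglech at -2.85 and Fscn1 at -2.73, and endothelial genes in 8 of 8, with Madcam1 at -2.91 in the authors' deposited table. With 1 library left out, Pck1 ran from -7.44 to -5.17, Car3 from -7.17 to -3.73, Cidec from -6.80 to -2.78, Cd209a from -5.54 to -4.47, Ccl22 from -5.59 to -4.38 and Siglech from -3.50 to -2.40, each lowest without the same tumour library. Scgb2b27 ran from 4.07 to 5.54 and Car6 from 3.61 to 4.76, both highest without the wild-type library with more reads.

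Single T cell genes stood out in both directions in this comparison. Gzmk was higher by 5.82, Il7r by 1.57, Pdcd1 by 1.42 and Tigit by 1.24, while Ccr7 (-0.80) and Cd8a (-0.74) were lower in the authors' deposited table. The proliferation genes Mki67 (0.64), Ccnb1 (0.75) and Top2a (0.42) were higher and Stmn1 (-0.68) was lower in the authors' deposited table. Lyz2 (-7.75), Serinc3 (-2.41) and Ifi202b (6.93) moved as in knockout lymph node in the authors' deposited table. Ifi202b had 0 and 4 reads in the wild-type libraries and was at 5.93 without the library at 0, with no finite value without the other.

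The authors called 1630 of about 22086 genes tested, 737 higher and 893 lower. Fisher's exact tests gave adjusted p = 1.6e-07 for immunoglobulin segments, 0.000159 for plasma cell, 0.000455 each for adipocyte and dendritic cell, 0.00144 for salivary gland, 0.00547 for ribosomal protein and 0.0431 for endothelial genes. Lymph node stroma (1 higher, 9 lower, adjusted p = 0.0943), natural killer (2 and 10, 0.208), naive T cell (1 and 7, 0.208), NF-kB (1 and 7, 0.208), cell cycle (4 and 1, 0.344), autophagy (2 and 1, 0.756) and T cell identity lists (3 and 6, 0.748) did not pass. The endothelial call was lost among genes with an adjusted p under 0.01 (0.145) and among genes at least 2-fold apart (0.189), where the ribosomal call was lost too (0.789), and these settings left 983 genes (409 higher, 574 lower) and 771 genes (387 higher, 384 lower). All 1630 genes had libraries of the 2 groups that did not overlap, against 33.3% of random orders.

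The knockout against wild-type comparisons shared called genes, most of them in the same direction. B and T cells shared 92 called genes, of which 90 (97.8%) moved the same way, where independent lists of these sizes would give 3.33 (two-sided exact binomial test of direction, p = 1.7e-24, over genes that are not independent). B cells and lymph node shared 49, with 48 the same way, and T cells and lymph node shared 51, with 50 the same way, where independent lists would give 0.743 and 1.3. A set of 30 genes was called in all 3 tissues, each in 1 direction throughout, 25 lower and 5 higher in the knockout. It held 13 immunoglobulin variable segments, the lysozyme pair Lyz2 and Lyz1 on chromosome 10, Serinc3 on chromosome 2, Xkr6 on chromosome 14, and Gas5, Gm4955, Pydc4, Pyhin1 and Pydc3 on chromosome 1. Of these 30 genes, 29 were called in the same direction in tumour against wild-type lymph node, and 1, Igkv1-135, was called in tumour against knockout lymph node. Among comparisons with no common library, B cells shared 120 called genes with tumour against wild-type lymph node, 107 the same way beside 11.2 for independent lists, and 21 with tumour against knockout lymph node, 15 the same way beside 2.76. T cells shared 245, 204 the same way beside 20.8, and 87, 55 the same way beside 4.74. At an adjusted p under 0.01 the same-direction counts of these 4 pairs moved by over 1.5 times in 3, to 68, 5 and 128 in place of 107, 15 and 204.

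Comparisons with common libraries also overlapped. Knockout lymph node and tumour, both against wild-type lymph node, shared 80 called genes with 79 the same way, beside 3.96 for independent lists. Tumour against each of the lymph node groups shared 328, all the same way, beside 15.7, and 199 at an adjusted p under 0.01 and 212 at a fold of at least 2. In simulated unchanged groups that shared libraries in these ways, with an assumed dispersion of 0.1, 65.7% and 65.6% of all genes had the same sign. Each simulated comparison made only 0 to 3 calls. That 0 calls were shared there was thus fixed in advance and is no measure for the longer real lists. Knockout lymph node stood on opposite sides of the remaining pair, which shared 22 called genes, 12 the same way and 10 opposite. Independent lists would give 1.04 the same way, and 32.1% of all genes had the same sign in the simulation of this pair. The shared groups held only 2 libraries and could not be split, so part of the excess may come from shared libraries.

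**Figure D4:**
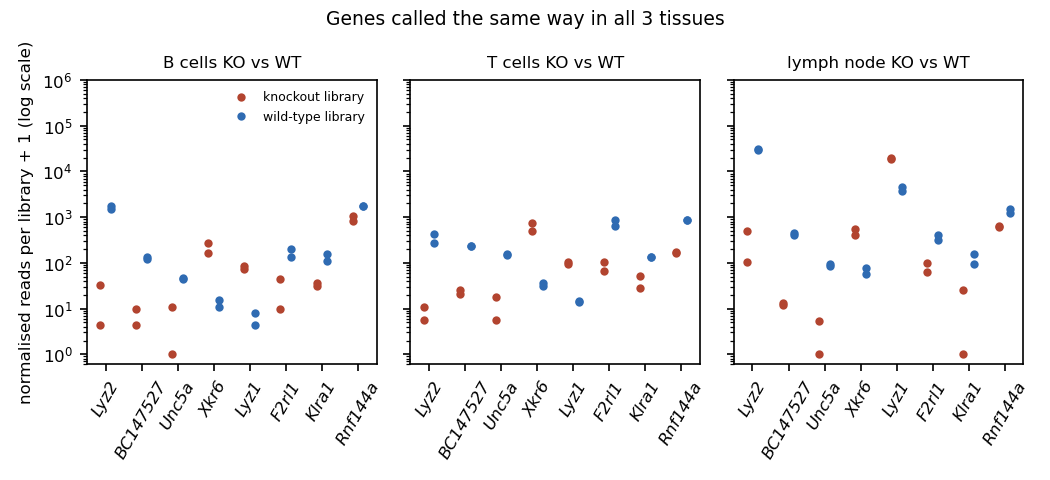
Normalised reads per library plus 1 (vertical axis, log scale), recovered from the authors' group means, for 8 genes (horizontal axis) called in the same direction in B cells, T cells and lymph node. Red points are the 2 knockout libraries and blue points the 2 wild-type libraries of each tissue, and the genes were picked by the size of their smallest change over the 3 tissues, among genes with reads recovered in every library.

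Called genes were counted around the targeted locus and by chromosome. Becn2 lies on chromosome 1 from 175920329 to 175922225 (GRCm38), and the region within 10 Mb of it on each side, from 165920329 to 185922225, holds 476 annotated genes. Within it lay 10 called genes in B cells (odds ratio 4.14), 11 in T cells (2.26), 8 in lymph node (9.69) and 31 in tumour against wild-type lymph node (2.34), with adjusted p = 0.000427, 0.0239, 1.9e-05 and 0.000116 by two-sided Fisher's exact test. Tumour against knockout lymph node, where both groups are knockout, had 4 (odds ratio 1.12, adjusted p = 0.785). The share of called genes over the share of annotated genes was 2.14 on chromosome 1, 2.60 on chromosome 6, with the kappa locus, and 3.66 on chromosome 12, with the heavy chain locus, in B cells. In the same order it was 1.11, 2.53 and 2.42 in T cells, 1.38, 2.03 and 5.76 in lymph node, and 1.40, 1.48 and 1.20 in tumour against wild-type lymph node, with no test. In tumour against knockout lymph node, with knockout on both sides, it was 1.24, 2.09 and 1.35, so these shares are not tied to genotype alone. Pydc4 (173566283 to 173599274), Pyhin1 (173630917 to 173647928) and Pydc3 (173673675 to 173698395), of a cluster of interferon-inducible genes, were called lower in B cells, T cells and lymph node. Other members of the cluster were higher in some tissues, with Ifi204 higher in B cells (2.45) and T cells (2.70) in the authors' deposited table, Ifi202b called higher in T cells and lymph node, and Mnda higher in B cells and lower in lymph node. Ifi204 in T cells ran from 2.27 to 3.33 with 1 library left out, highest without the wild-type library with more reads. By direction the window held 2 higher and 8 lower genes in B cells, 6 and 5 in T cells, 2 and 6 in lymph node and 6 and 25 in tumour against wild-type lymph node. The tests treat genes as independent, which neighbours are not, and this cluster supplied many of the calls. Its called members included Pydc4, Pydc3, Pyhin1, Ifi204, Mndal and Mnda in B cells. In T cells they included Pydc4, Pydc3, Pyhin1, Ifi204 and Ifi202b, and in lymph node Pydc4, Pydc3, Pyhin1, Ifi202b and Mnda. The background was every annotated gene, expressed or not, since the tables listed called genes only, and the T cell call was lost with 20 Mb on each side (14 genes, adjusted p = 0.164).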

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

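All tests of explanations in this part were chosen after the result was seen, except the test of coding length, which was written down before it was run. Of the genes called in more than 1 of B cells, T cells and lymph node, 4 moved in opposite directions with libraries that did not overlap, and these differences between tissues were not tested. Irf4, a regulator of plasma cell formation, had a log2 fold change of -0.77 in B cells and 1.08 in T cells. Myof was at -1.76 in B cells and 1.30 in T cells. Mnda, of the interferon-inducible cluster near Becn2, was at 1.66 in B cells and -2.27 in lymph node. Fam84b was at -0.99 in T cells and 1.12 in lymph node, and all of these values are from the authors' deposited tables.

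The first pattern weighed is the set of 30 genes called the same way in B cells, T cells and lymph node. A segment next to Becn2 carried along with the targeted allele cannot be the only source, because 25 of the 30 genes lie on 7 other chromosomes. A strain background that differs from the wild type at several loci, although the labels name 1 strain, and loss of Beclin 2 in each tissue both predict that few of these genes differ between knockout tumour and knockout lymph node, and 1 of the 30 was called there. Of 47 listed transcripts known to vary between mouse substrains, 6 were called in B cells, 7 in T cells, 6 in lymph node and 13 in tumour against wild-type lymph node. In tumour against knockout lymph node 1 was called. Called genes were 1.24%, 2.35%, 0.475%, 7.38% and 1.77% of genes tested, in that order. Enrichment was not tested, and Pydc4, near Becn2, was among those called against wild type. The 2 explanations cannot be told apart, since a background difference, if present, would go with genotype in every knockout group. Called heavy chain variable segments at 0 reads in both knockout libraries numbered 20 of 34 in B cells, 10 of 38 in T cells, where 3 others were at 0 in wild type, and 10 of 22 in lymph node, with no comparison group, because no called kappa segment was lower.

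The second pattern is the salivary gland transcripts in tumours. Tumour cells as the only source are argued against by wild-type lymph node, where 7 of the 11 genes had a mean of at least 50 normalised reads. Gland tissue taken along with the dissected samples may add to them: 8 of the 10 genes listed against knockout lymph node had more normalised reads in the same knockout lymph node library. Bhlha15 pointed to the other library, and Prol1 was at 0 in both and could point to neither. Bhlha15 was also the 1 gene of this list called in T cells, higher in the knockout, so its reads need not come from gland. In wild-type lymph node 11 of 11 genes had more in the same library, and in the tumours 9 of 10. The test asked for all 10 in the knockout node, which could not be met with Prol1 at 0 in both libraries. Expression that differs between samples would give the same split, so the source cannot be told apart on these values.

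The third pattern is the lower ribosomal protein genes in knockout T cells, to which a loss of reads from short coding genes may contribute: 32.4% of 176 other called genes no longer than the longest called ribosomal protein gene were lower, against 14.3% of 238 longer ones (Fisher's exact p = 1.4e-05). In tumour against wild-type lymph node short genes leaned lower too (68.2% against 54.4%) although ribosomal protein genes were higher there, and in tumour against knockout lymph node short genes leaned higher with them (28.6% of 14 lower against 69.4% of 353). The cut followed the longest called ribosomal protein gene, at 1209 coding bases in T cells. It was 951 against wild-type and 330 against knockout lymph node, so short genes are not the same class in each. A lower cut was not tried in T cells. A smaller share of T cells stays open: plasma cell (11 of 11), neutrophil (9 of 9) and monocyte genes (15 of 16) were higher and receptor segments lower in 9 of 10. Of all 587 called genes 418 were higher, and the 3 higher lists did not pass Fisher's exact test (adjusted p = 0.133, 0.194 and 0.157). Their counts alone therefore decide nothing. Of 29 T cell identity genes only 2 were called, Cd8b1 and Trbc1, both lower, too few for a test. Against a smaller share, dendritic cell genes were 1 higher and 2 lower (adjusted p = 0.365), too few to decide. They were Klrd1, Ccr9 and Tmem176b, and Klrd1 is also on the natural killer list, so these lists are not separate evidence. Natural killer genes were lower as well, with an adjusted p of 0.0871 by Fisher's exact test for the 3 left without Klra1, which belongs to the first pattern. A change of T cell state stays open too. Naive T cell genes were 0 higher and 3 lower (adjusted p = 0.0871) and checkpoint genes 5 higher and 0 lower (0.515), the opposite directions it predicts. Effector and memory genes were 6 higher and 2 lower. The checkpoint test could not decide, because most called genes in T cells were higher: even 10 members all higher give an unadjusted Fisher's exact p of 0.0702.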

How the results depend on the processing

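The settings in this part were planned before the data were examined, except leaving out single libraries and leaving Klra1 out of the natural killer list in T cells (adjusted p = 0.0871), which were added after they were seen. At an adjusted p under 0.01 the tumour comparisons kept 273 genes against knockout lymph node and 983 against wild-type lymph node, at a fold of at least 2 the latter kept 771, and lymph node kept 65 genes without predicted genes and receptor segments, in each case because fewer genes can pass. The other counts of called genes by comparison stayed within 1.5 times, while of the counts by direction 30 stayed and 10 moved, and of the same-direction overlaps 35 stayed and 5 moved. The number of list directions past the threshold was 23, and 18, 17 and 23 at an adjusted p under 0.01, a fold of at least 2 and a mean of at least 50. Among list directions that could still be tested none turned, and across the planned settings 56 tests kept the call and 11 lost it. Lists left with too few called members could not be tested and are in neither count. Immediate-early genes in T cells at a fold of at least 2 are such a case. The genes shared by B and T cells with the same direction numbered 90, and from 63 to 90 under the alternatives. With a window of 5 Mb around Becn2, tumour against knockout lymph node turned from slightly more to fewer called genes than the annotation share, with 1 gene (adjusted p = 0.729), and the cause was not tested. Of 423 fold changes of named genes, 405 moved by at most 0.5 with a pseudocount of 1, 18 moved more and none changed sign. Leaving out 1 recovered library at a time, a value with no test, the genes at least 2-fold apart ran from 228 to 246 in B cells, 347 to 418 in T cells, 85 to 87 in lymph node, 299 to 333 in tumour against knockout lymph node and 724 to 834 in tumour against wild-type lymph node. Of 567 folds of named genes with recovered reads, 410 stayed within 1.5 times whichever library was left out and 157 did not, with a group left at 0 reads in 41 of these, and no finite value changed sign. No paired analysis was possible because the tables give 1 mean per group and the recovered libraries carry no replicate number. Alternatives planned for counts per library, namely DESeq2 in place of edgeR, the low-count filter, the replicate block and refits without a replicate, were not run, since the tables hold group means of called genes only. Depth limits the genes with a group at 0 reads, 28 in B cells, 19 in T cells, 12 in lymph node, 15 in tumour against knockout and 43 in tumour against wild-type lymph node, whose folds are bounds.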

Other observations

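The observations in this part were all chosen after the values were seen, and no explanation was tested for them. Gzmk, a granzyme of effector T cells, was higher in every comparison but lymph node, where it was not listed. In the authors' deposited tables its log2 fold change was 2.09 in B cells, 2.93 in T cells, 2.80 in tumour against knockout lymph node and 5.82 in tumour against wild-type lymph node. Apol7c, an apolipoprotein L gene, was lower in knockout T cells (-5.51), in tumour against knockout lymph node (-4.19) and in tumour against wild-type lymph node (-5.87), all from the authors' deposited tables. With 1 recovered library left out, Gzmk ran from 2.44 to 3.67 in T cells and from 2.31 to 3.55 in tumour against knockout lymph node, highest without the library with more reads in the lower group. Apol7c had 128 and 7 reads in the tumour libraries and ran from -7.41 to -3.27 and from -9.10 to -4.95 in the tumour comparisons, and from -6.14 to -5.07 in T cells. Postn, a matrix protein of fibroblasts, was higher in knockout T cells (3.47) and lower in both tumour comparisons (-2.79 and -2.99) in the authors' deposited tables.

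Rpl3 and its processed copy Rpl3-ps1 on chromosome X moved apart in T cells. The authors' deposited table gave Rpl3 a mean of 19495 normalised reads in knockout and 46572 in wild type, and Rpl3-ps1 a mean of 7072 and 226.6. Rpl3-ps1 was also higher in knockout lymph node (2.92) and in tumour against wild-type lymph node (3.99), where Rpl3 itself was not listed in the authors' deposited table. Reads of these copies can be divided between them, so the level of either is uncertain.

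Gas5, a noncoding host of small nucleolar RNAs on chromosome 1 from 161034422 to 161038539, was lower by a similar amount in each knockout against wild-type tissue, with -2.20 in B cells, -2.11 in T cells and -2.27 in lymph node in the authors' deposited tables. Ccnb1ip1 on chromosome 14 had 0 reads in both wild-type B cell libraries and 42 and 16 in the knockout libraries, at least 23.0-fold higher, and in T cells 3 and 0 reads in wild type against 100 and 45, a ratio of 50.8 with a 95% exact counting interval from 17.1 to 249.4.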
